A study of Mus musculus with 6 samples.

How the data were processed

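RNA-seq was done on integrin α6-positive epidermal cells sorted from newborn mice (postnatal day 0). Per the labels, 3 libraries came from control animals carrying K14Cre and 1 floxed Ash2l allele, and 3 from conditional knockout (cKO) animals with both alleles floxed. Groups and replicate numbers were taken from the labels. Nothing states that each library came from a separate animal, so p-values measure the spread between these libraries. The library labelled control 1 held 5 Y-linked fragments against 5703 and 7120 in control 2 and 3, so it was not a repeat library of either. Whether the other libraries came from separate animals is not settled here. The targeted gene went against the labels, and groups are therefore called "the libraries labelled cKO" and "the libraries labelled control"; no library was moved.

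The authors deposited 1 table of FPKM values (fragments scaled to the length of the gene model and the total of the library) for 17025 genes, per the file headers. The submitters' processing notes name fastp, HISAT2, HTSeq and the genome build GRCm39, with no versions. The annotation release, the gene filter and the use of strand are not given in the sources used here. Reads of overlapping genes and of near-identical paralogues (keratin 6, small proline-rich, cystatin A and haemoglobin genes among them) are uncertain for that reason. The reference table at hand is of GRCm38, another build; it was used for names and neighbours and no coordinates are printed. Of the genes, 16932 had an identifier in that table.

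Low FPKM values were whole multiples of the worth of 1 fragment. Gene lengths and library totals that turn the values into whole fragments, within a tolerance of 1e-09, were found for 17024 genes. The totals were 31578875, 33053422 and 32792756 fragments in the libraries labelled control 1, 2 and 3, and 33622416, 34043672 and 36027550 in those labelled cKO 1, 2 and 3. No pair of libraries differed by as little as sampling noise: the closest pair, labelled cKO 1 and 2, had a chi-square per gene of 14.4.

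Genes with a mean of at least 1 FPKM over the 6 libraries (11603) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with group as the only term and a mean-variance trend. Adjusted p-values are Benjamini-Hochberg values from this fit, called under 0.05. Differences are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Of 28 gene lists, 24 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the 24. Members were counted over all genes tested and adjusted over the list alone. Fisher's exact test, one-sided, compared the members among the calls with all genes tested, over 48 tests.

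The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Ash2l; the 10 largest rises and the 10 largest falls among called genes with a group mean of at least 5 FPKM and no overlap of the groups, leaving out predicted, Rik, pseudogene, mitochondrial and haemoglobin genes; the 4 members of each list with the smallest adjusted p; and a set of Notch, keratinocyte and hair follicle genes. One gene that the rule takes is not reported here. The alternatives covered pseudocounts of 0.1 and 0.01, other filters, 3 scalings, other variance settings, a replicate block, each library left out, other thresholds and other list tests. Chosen after seeing the data were limma-voom on the recovered fragments with each of 2 scalings, a fit on 4 libraries, and enrichment of pathway terms from the authors' annotation. The 4 libraries were the closest pair within each labelled group, control 2 and 3 and cKO 1 and 2. More calls in that fit may follow from the smaller spread of the libraries kept and are not independent support.

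The gene test was tested on simulated data for the comparison of 3 with 3 libraries over 11584 genes. It recovered 4% of genes changed 1.5-fold, 28% at 2-fold, 80% at 4-fold and 92% at 8-fold, and 8.1% of its calls were unchanged genes. Only 50 genes were changed at each fold, and 111 calls were made, against 2257 in the data. Fewer changed genes make the Benjamini-Hochberg cut-off stricter, so these shares need not hold for the data. In a second simulation camera called 3 of 3 shifted lists and none of the others. Its genes were drawn independently, so it could not show false calls that come from correlation between genes. Figures were drawn with matplotlib 3.10.9.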

Results

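Gene expression was measured by RNA-seq in integrin α6-positive epidermal progenitor cells from newborn mice. Integrin α6 is a receptor that anchors basal keratinocytes to the basement membrane. There were 3 libraries labelled control and 3 labelled cKO, with 31578875 to 36027550 fragments each. The series addresses how ASH2L, a core subunit of the histone H3 lysine 4 methyltransferase complexes, acts on epidermal differentiation, hair follicle formation and Notch signalling.

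Ash2l was higher in the libraries labelled cKO than in those labelled control, against the labels. It stood at 12.4, 18.1 and 15.9 FPKM in the libraries labelled control 1, 2 and 3, and at 30.9, 29.5 and 22.9 FPKM in those labelled cKO 1, 2 and 3. The means were 15.5 and 27.8 FPKM, a log2 difference of 0.81 (SE 0.19, n = 3 per group; limma adjusted p = 0.024). The exact permutation test, two-sided, gave p = 0.1, the smallest that 3 against 3 can give. A gene total cannot show whether a floxed exon was lost. Without the library labelled control 1, control 3, cKO 1 or cKO 2 the adjusted p was 0.0560, 0.0665, 0.0829 or 0.0810. Every direction below is drawn from labels that the targeted gene went against.

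**Figure D1:**
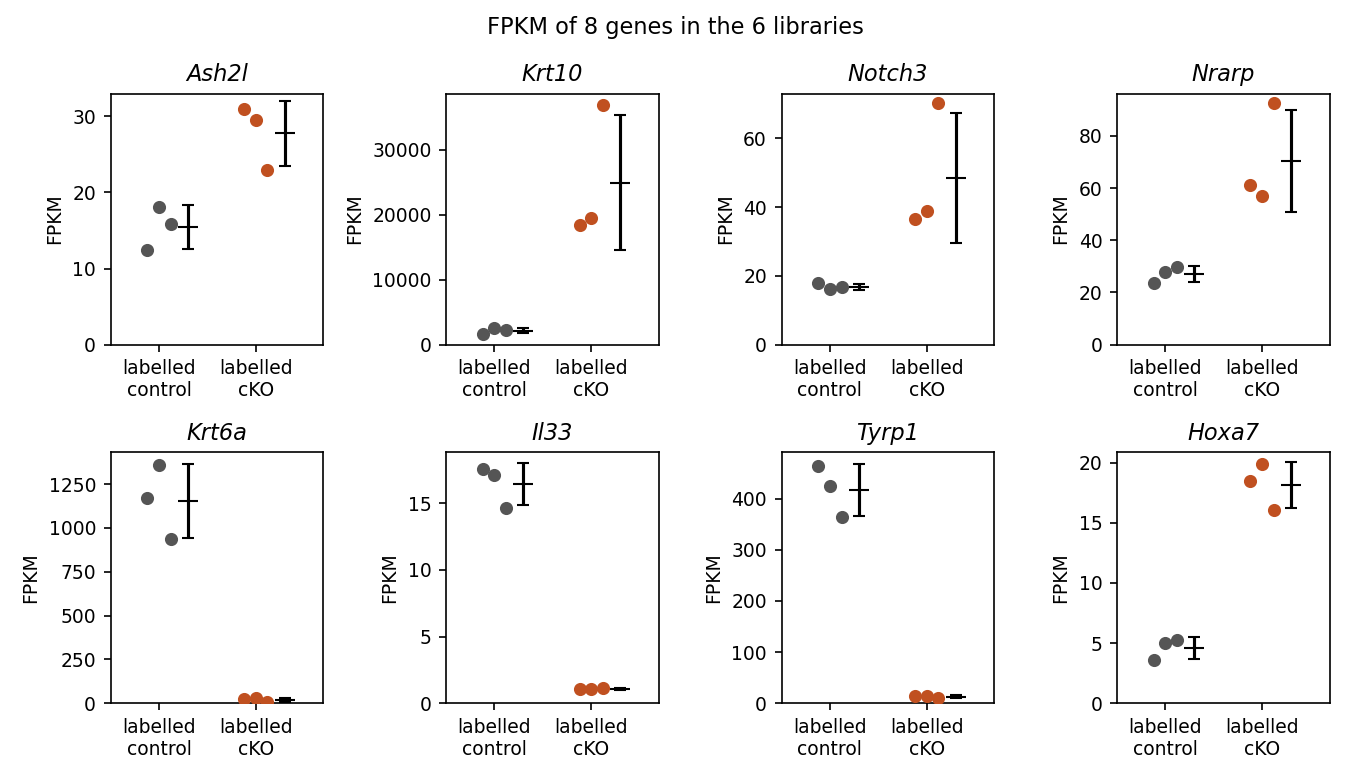
FPKM (vertical axes, from 0) of 8 genes in each library; points are libraries, and the bar beside them is the mean with its SD (n = 3). Ash2l lay between 12.4 and 18.1 in the libraries labelled control and between 22.9 and 30.9 in those labelled cKO.

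Krt10, a keratin of spinous cells, averaged 2158 FPKM in the libraries labelled control and 24890 FPKM in those labelled cKO (log2 difference 3.47, SE 0.28, adjusted p = 0.000794). Krt6a, a keratin of wounded epidermis, averaged 1153 and 19.5 FPKM (-5.96, SE 0.40, adjusted p = 0.000676). The other largest rises were Npl (3.32), Postn (3.24), Tfap2e (3.20), Gpt (3.16), Adh1 (3.12), Krt1 (3.12), Penk (3.09), Acer1 (3.09) and Krt77 (3.05). The other largest falls were Krt6b (-5.22), Tyrp1 (-4.92), Serpinb2 (-4.39), Mlana (-4.30), Ly6a (-4.27), Csta3 (-4.04), Sprr1b (-3.82), S100a9 (-3.78) and Bst2 (-3.72). Of 11603 genes tested, 681 were higher and 1576 lower in the libraries labelled cKO. The median of all genes lay at -0.17, and scaling by the median of ratios moved it to -0.02 and the calls to 941 higher and 1103 lower. Krt1 and Krt10 together took 8.0 to 16.2% of the FPKM sum in the libraries labelled cKO and 0.9 to 1.3% in those labelled control. Each library averages over its sorted cells, so a larger share of spinous cells cannot be told apart from higher expression per cell. The total of 2257 calls fell to 1102, 1251, 1376 and 1318 without the libraries labelled control 2, control 3, cKO 1 and cKO 2, and was 3576 on the 4 libraries labelled control 2 and 3 and cKO 1 and 2.

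Of 24 lists, 14 were called by camera, and none of them with an estimated correlation; the adjusted p so obtained is given for each list called. By Fisher's exact test 8 of the 14 were enriched among the calls in the same direction (adjusted p up to 0.00344): spinous, lipid barrier, hair placode and Hox genes among the higher, and p53, stress, interferon and melanocyte genes among the lower. The other 6 were not, with adjusted p = 0.479 for hair shaft, 0.467 for Wnt, 0.723 for Hedgehog, 0.305 for Schwann cell and 1 for fibroblast and ribosomal genes. Spinous and desmosome genes had 12 members higher and 3 lower of 29 (16 and 4 adjusted over the list alone; median 0.44, camera adjusted p = 2.82e-07, and adjusted p = 0.314 with an estimated correlation). Krtdap rose by 1.46 and Lgals7 by 1.79, while Serpinb2 fell. Epidermal lipid barrier genes had 7 higher and 3 lower of 26 (11 and 4 adjusted over the list alone; camera adjusted p = 0.00127, and adjusted p = 0.297 with an estimated correlation), among them the ceramidase gene Acer1, Dgat2 (2.06) and Elovl4 (1.01), with Plb1 lower (-1.68). Lipid barrier genes had 3 higher without the library labelled control 2 and 12 on the 4 libraries, where spinous genes had 15 higher and 6 lower. Granular and cornified envelope genes went both ways, 6 higher and 9 lower of 29 (7 and 9 adjusted over the list alone), with 3 higher without the library labelled control 2. Scel rose by 1.10 and Flg, which encodes filaggrin, by 1.82, while Klk5 (-1.82), Sprr1a (-2.53) and Sprr2h (-3.25) were lower. The median (-0.02) and mean (-0.29) of that list lay below 0 while camera pointed up (adjusted p = 0.392). The sign of the median was not stable: 0.24 without the library labelled control 3, 0.29 without cKO 3 and -0.13 without cKO 1. Fisher's exact test found the granular list enriched among the higher calls (adjusted p = 0.0317) and not among the lower (adjusted p = 0.0524). Lor was at 1.81 (SE 0.56, adjusted p = 0.0559), and at 2.44 without the library labelled cKO 3, where it was called (adjusted p = 0.00826). Ivl was at 0.25 (SE 0.31, adjusted p = 0.608).

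Basal keratinocyte and hemidesmosome genes had 2 members higher and 4 lower of 28 (2 and 5 adjusted over the list alone; camera adjusted p = 0.588). Krt15 rose by 2.23 and Postn by 3.24, and Itgb4, the partner of integrin α6 in hemidesmosomes, was lower (-1.70, SE 0.48, adjusted p = 0.0438), as were Cd151 (-0.70) and Ifitm3 (-2.51). The call of Itgb4 was lost without the library labelled control 1, 2 or 3 (adjusted p = 0.125, 0.103 and 0.0936) and in 8 of 21 alternatives in all, scaling by the median of ratios among them (adjusted p = 0.0517). Itgb4 stood at -1.09 without cKO 3 and at -0.86 on the 4 libraries. Cd151 lost its call without control 3, cKO 1 or cKO 2 (adjusted p up to 0.0592) and Ifitm3 without control 1 or 2 (adjusted p up to 0.0573). The 4 lower became 2 without the library labelled control 1 and 1 without control 2 or control 3, and 2 under scaling by the median of ratios. On the 4 libraries labelled control 2 and 3 and cKO 1 and 2, 5 were higher and 7 lower, and the median of -0.48 became 0.01. Differences did not pass the test for Itga6 (-1.32, SE 0.44, adjusted p = 0.0710), Krt5 (0.51, SE 0.24), Krt14 (-0.08, SE 0.24) and Trp63 (0.40, SE 0.23), though on the 4 libraries Itga6 (-0.49), Krt5 (0.60) and Trp63 (0.74) were called.

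Stress and wound keratinocyte genes had 14 members lower and 1 higher of 20 (15 and 1 adjusted over the list alone; median -1.73, camera adjusted p = 2.95e-06, and adjusted p = 0.0886 with an estimated correlation). The cytokine genes Il33 (-3.06) and Tslp (-3.57) were among them. Interferon response genes had 16 lower and none higher of 21 (18 and 0 adjusted over the list alone; median -1.58, camera adjusted p = 4.05e-09, and adjusted p = 0.0581 with an estimated correlation), with Bst2, Gbp2 (-2.18), Rsad2 (-1.99) and Cxcl10 (-2.23) lower. Of 29 p53 target genes, 12 were lower and 2 higher (16 and 2 adjusted over the list alone; camera adjusted p = 0.0160, and adjusted p = 0.312 with an estimated correlation): Bax (-0.99), Plk2 (-1.30) and Dcxr (-1.85) fell and Perp, also a desmosome gene, rose by 1.07. Cdkn1a was at -0.24 (SE 0.16). With genes of at least 5 FPKM alone camera did not call the p53 list (adjusted p = 0.0600). The 12 lower p53 targets became 6 without the library labelled control 1 or control 2, 4 without control 3 and 5 without cKO 1 or cKO 2, with 1 higher in each. There were 8 under scaling by the median of ratios and 17 on the 4 libraries labelled control 2 and 3 and cKO 1 and 2.

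Within the Notch pathway, Notch3, Heyl and Nrarp were higher in the libraries labelled cKO, and the receptors Notch1 and Notch2 did not pass the test. Notch3 averaged 16.9 and 48.6 FPKM (1.41, SE 0.25, adjusted p = 0.00852), Heyl rose by 1.62 (SE 0.23) and Nrarp, a feedback regulator, by 1.31 (SE 0.20). Notch target genes had 4 higher and 1 lower of 15 (4 and 3 adjusted over the list alone; camera adjusted p = 0.124), the others called being Gata3 (0.79) and Myc (-0.93). Camera called them with the filter at 0.1 FPKM (adjusted p = 0.0297) or no filter (adjusted p = 0.0464). They were enriched among the higher calls by Fisher's exact test (adjusted p = 0.0458). Of 31 ligands, receptors and components, 2 were higher, Notch3 among them, and 1 lower, Psen2 (means 26.7 and 6.03 FPKM), the same numbers being called adjusted over the list alone; the median was 0.00, the mean -0.05 and camera pointed up (adjusted p = 0.338). On the 4 libraries labelled control 2 and 3 and cKO 1 and 2, Notch targets had 5 higher and 4 lower and the components 4 and 3. Notch1 was at -0.16 (SE 0.14), Notch2 at 0.12 (SE 0.22), Jag1 at -0.45 (SE 0.17), Jag2 at -0.56 (SE 0.64), Dll1 at 0.48 (SE 0.40), Rbpj at -0.24 (SE 0.27), Hes1 at 0.61 (SE 0.35) and Hey1 at 1.03 (SE 0.50). Hes1 was called without the library labelled control 1 (1.07, adjusted p = 0.00965), Dll1 without cKO 3 (0.96, adjusted p = 0.0261) and Jag1 on the 4 libraries (-0.50, adjusted p = 0.0187).

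Hair placode, germ and follicle stem cell genes had 9 members higher and 1 lower of 29 (10 and 2 adjusted over the list alone; camera adjusted p = 0.000248, and adjusted p = 0.466 with an estimated correlation). Krt79 rose by 2.50, Foxi3 by 2.31, Sostdc1 by 1.85 and Barx2 by 0.58. Shh (1.60, SE 0.47, adjusted p = 0.0491) and Wnt10b (1.41, SE 0.41, adjusted p = 0.0474) lay close to the threshold, and Edar (1.02, SE 0.38), Lhx2 (0.76, SE 0.51), Lef1 (-0.45, SE 0.47) and Sox9 (-0.50, SE 0.18) did not pass it. On the 4 libraries labelled control 2 and 3 and cKO 1 and 2 the list had 15 higher and 2 lower. Its 9 higher became 2 without the library labelled control 2, 3 without control 3 or cKO 1 and 4 without cKO 2. The list mean, in log2(FPKM + 1), was 4.18 and 4.23 in the libraries labelled cKO 1 and 2. In cKO 3 it was 3.43, within the range of those labelled control (3.65, 3.21 and 3.63). Edar (1.45) and Lhx2 (1.33) were called without cKO 3 (adjusted p = 0.00760 and 0.0413), where Sostdc1 lost its call (adjusted p = 0.0516). Hair shaft and inner root sheath genes had 3 higher (Dsc3, Gata3, Lap3) and 3 lower, S100a3 among them, of 23, the same numbers adjusted over the list alone (camera adjusted p = 0.0368; 0.0570 without the library labelled control 1 and 0.0755 without control 2, 0.143 under scaling by the median of ratios and 0.0573 on the 4 libraries, and adjusted p = 0.297 with an estimated correlation). Leaving out cKO 3 gave 6 hair shaft genes higher, leaving out control 2 or cKO 2 gave 1 lower, and the 4 libraries gave 7 higher and 6 lower. The hair shaft mean in cKO 3 (2.52) also lay within the range of those labelled control (2.53, 2.44 and 2.72), against 2.77 and 2.78 in cKO 1 and 2. Canonical Wnt genes had 4 higher and 1 lower of 34 (2 and 1 adjusted over the list alone; camera adjusted p = 0.0166, and adjusted p = 0.667 with an estimated correlation): Sfrp1 (2.05), Fzd6 (0.59), Fzd10 (0.88) and Wnt10b rose and Dkk3 fell by 2.58. Without the library labelled cKO 1 or cKO 2 that call was lost (adjusted p up to 0.0941), and without either of these, control 2 or control 3, 1 Wnt gene was higher, against 12 on the 4 libraries. The Wnt list mean was 4.2 and 4.22 in the libraries labelled cKO 1 and 2. In cKO 3 it was 3.35, below all those labelled control (3.75, 3.65 and 3.98). Hedgehog genes had 2 higher (Shh, Gas1) and 1 lower (Boc) of 16 (1 and 0 adjusted over the list alone; camera adjusted p = 0.0448, and adjusted p = 0.667 with an estimated correlation). Camera did not call the Hedgehog list without control 1, control 2, cKO 1 or cKO 2 (adjusted p = 0.0570, 0.108, 0.102 and 0.136), nor under scaling by the median of ratios (adjusted p = 0.107) or quantiles (adjusted p = 0.0978). The count was 7 higher and 2 lower without the library labelled cKO 3 (median 0.93 against 0.52), 1 and 0 without control 1, cKO 1 or cKO 2 (medians 0.35, 0.33 and 0.33), 0 and 0 without control 2 or control 3, and 8 and 3 on the 4 libraries. The Hedgehog list mean in cKO 3 (3.03) also lay below all those labelled control (3.41, 3.24 and 3.6), against 4 and 4.09 in cKO 1 and 2. The mean of fibroblast and dermal condensate markers was likewise lower in cKO 3 (3.58) than in cKO 1 and 2 (5.12 and 4.93). In the libraries labelled control it was 2.86, 3.91 and 4.79. That mean was not a term in the fits of the lists in this paragraph, so its part in their shifts was not tested. Of the called genes named in this paragraph, Shh, Wnt10b, Barx2, Sostdc1, Lap3, Fzd6, Fzd10, Gas1 and Boc lost their calls without control 2 (adjusted p up to 0.156), and these and Dkk3 without control 3 (adjusted p up to 0.124). Shh, Wnt10b, Lap3, Fzd6, Fzd10 and Boc also lost theirs without cKO 1 or cKO 2 (adjusted p up to 0.132), Barx2 without cKO 1 (adjusted p = 0.0759), and Shh, Dkk3 and Boc without control 1 (adjusted p up to 0.106).

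**Figure D2:**
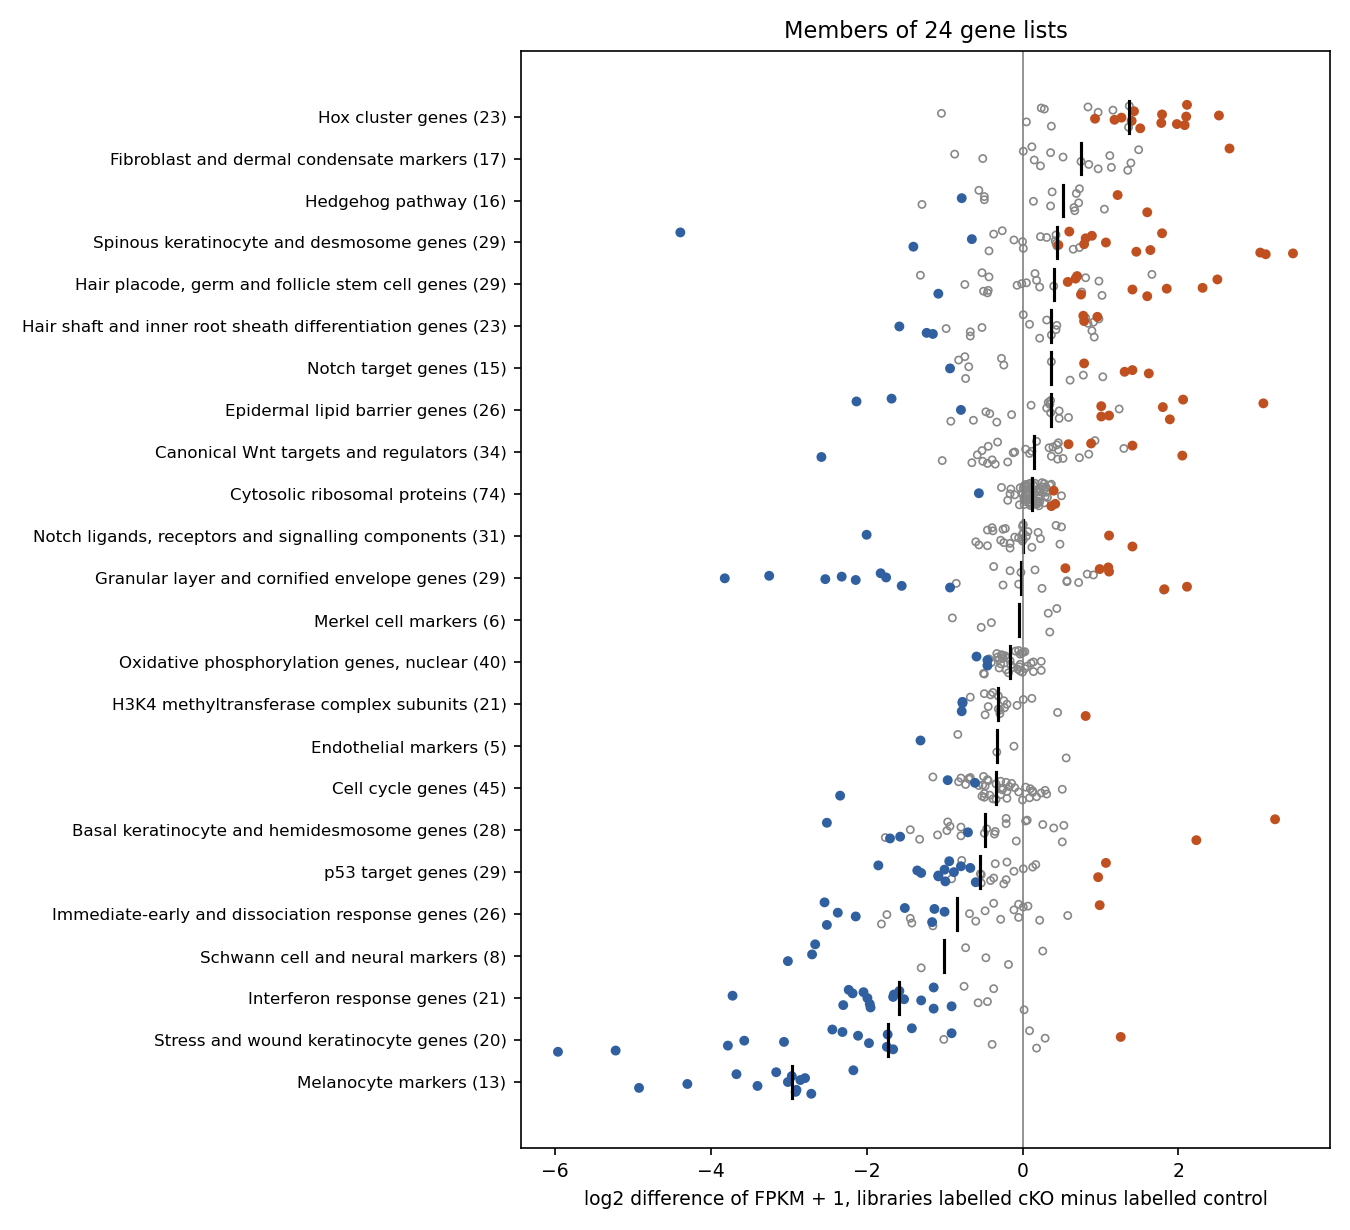
Log2 difference of each tested member (points; horizontal axis, libraries labelled cKO minus labelled control) in 24 gene lists, with the number of members in brackets. Filled points passed adjusted p under 0.05 (red higher, blue lower), open points did not, and black bars are medians; the medians run from -2.96 for melanocyte markers to 1.36 for Hox genes.

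Hox cluster genes had 13 members higher and none lower of 23 (17 and 0 adjusted over the list alone; median 1.36, camera adjusted p = 5.07e-12, and adjusted p = 0.188 with an estimated correlation). These transcription factor genes are known for positional identity along the body axis. Hoxa7 averaged 4.59 and 18.1 FPKM (1.78, SE 0.19), and Hoxb6 (2.10), Hoxb7 (2.52) and Hoxb8 (1.79) were below 1 FPKM on average in the libraries labelled control. The 13 became 8 without the library labelled cKO 1. Of 21 subunits of the H3K4 methyltransferase complexes, Ash2l was higher and Cxxc1 (-0.77), Kmt2a (-0.78) and Psip1 (-0.77) were lower (2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.208), with 1 lower without the library labelled control 2 or cKO 1, and 6 on the 4 libraries labelled control 2 and 3 and cKO 1 and 2. Cxxc1 lost its call without control 2 (adjusted p = 0.0503), Kmt2a without control 2 or cKO 1 (adjusted p up to 0.0578) and Psip1 without control 1, control 3 or cKO 1 (adjusted p up to 0.0708). Of 45 cell cycle genes, Cdk2, Pcna (-0.61) and Gins2 (-0.96) were lower and none higher (2 and 0 adjusted over the list alone; camera adjusted p = 0.200, and 0.0459 without the library labelled control 2), and Mki67 was at 0.00 (SE 0.24). The 4 libraries gave 5 cell cycle genes lower and 1 higher, and Gins2 was not called without control 1, 2 or 3 or cKO 2 (adjusted p of at least 0.0843). Cdk2 (-2.34) overlaps the melanocyte gene Pmel in the GRCm38 annotation, and its reads cannot be told apart from those of Pmel without strand. Of 40 nuclear oxidative phosphorylation genes, Cox6a1 (-0.59), Ndufv1 (-0.45) and Uqcrh (-0.45) were lower and none higher, with none called adjusted over the list alone (camera adjusted p = 0.348, but 0.0277 without the library labelled cKO 3 and 0.0463 with array weights); the median of -0.16 became 0.02 under scaling by the median of ratios, where 0 were lower. Leaving out the library labelled cKO 3 gave 6 lower, without cKO 1 or cKO 2 none, without control 1, control 2 or control 3 there was 1, and on the 4 libraries 12. Cox6a1 kept its call without control 3 or cKO 3, Uqcrh without control 1 or cKO 3 and Ndufv1 without cKO 3, and lost it without any other library (adjusted p up to 0.128 for Uqcrh).

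Markers of other cell types differed between the groups. All 13 melanocyte markers were lower in the libraries labelled cKO, over all genes and adjusted over the list alone (median -2.96, camera adjusted p = 2.03e-11, and adjusted p = 0.309 with an estimated correlation). Dct, a pigment enzyme gene, averaged 1261 and 175 FPKM (-2.91, SE 0.26), and Pmel (-3.40), Oca2 (-3.16) and Tyrp1 were lower as well. Schwann cell and neural markers had 3 lower of 8 (5 adjusted over the list alone; camera adjusted p = 0.00961, and adjusted p = 0.466 with an estimated correlation), namely Tubb3 (-2.66), Foxd3 (-2.70) and Sox10 (-3.01), the last also in the melanocyte list. Fibroblast and dermal condensate markers had 1 of 17 higher, Sox18 (2.65), and 0 adjusted over the list alone (median 0.75, camera adjusted p = 0.00537; 0.0921 with a median of 0.18 without the library labelled control 1, and adjusted p = 0.667 with an estimated correlation). Without the library labelled control 1, control 2, cKO 1 or cKO 2, 0 fibroblast markers were higher (medians 0.18, 0.51, 0.40 and 0.48; adjusted p of Sox18 up to 0.0991), and without control 3 or cKO 3 there were 2 (0.97 and 1.32). Their list means, in log2(FPKM + 1), were 2.86, 3.91 and 4.79 in the libraries labelled control and 5.12, 4.93 and 3.58 in those labelled cKO. Endothelial (1 lower of 5, Esam, with 2 without control 3 and 0 without any other library, adjusted p of Esam up to 0.0894; camera adjusted p = 0.536) and Merkel cell markers (0 of 6; camera adjusted p = 0.848) were not called. Of lists with under 5 tested members, leukocyte (1 member) and erythroid (3) had none called, 2 of 3 skeletal muscle genes, Tnni2 (-2.64) and Tnnt3 (-1.42), were lower (Tnnt3 lost its call without any library but control 3, adjusted p up to 0.0966), and the list of mitochondrially encoded genes had 0 members in the table.

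Libraries also stood apart within groups. Immediate-early and dissociation response genes averaged 5.19 in the library labelled control 1 against 3.94 and 4.06 in control 2 and 3, and 3.61, 3.50 and 3.46 in those labelled cKO. Of 26, 8 were lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.0725). Camera called the list without the library labelled control 2 (adjusted p = 0.0114) or control 3 (adjusted p = 0.0225). It also did so with the replicate block (adjusted p = 0.0199) and under scaling by the median of ratios (adjusted p = 0.0313) or quantiles (adjusted p = 0.0299). Without the library labelled control 1 the list median went from -0.84 to -0.14 (camera adjusted p = 0.313). On the 4 libraries labelled control 2 and 3 and cKO 1 and 2 it was -0.29 (camera adjusted p = 0.228). The lower genes included Klf6 (-1.51), Socs3 (-2.54), Ier3 (-2.14) and Nr4a1 (-2.37). The 8 became 5 without the library labelled control 3, cKO 1 or cKO 3 and 4 without cKO 2, and Socs3 lost its call without control 2 (adjusted p = 0.0516). Ribosomal protein genes shifted by a median of 0.12 (camera adjusted p = 4.68e-06, and adjusted p = 0.667 with an estimated correlation), with 3 higher (Rpl10, Rpl3, Rps9) and 1 lower (Rps2) of 74, and 0 adjusted over the list alone. Quantile normalization ended the camera call (median 0.06, adjusted p = 0.298). Scaling by the median of ratios gave 17 higher and 1 lower (median 0.30). Leaving out the library labelled cKO 3 gave 13 and 2 (median 0.22), on the 4 libraries 20 and 2, and without any other library 0 higher (median 0.07 without control 1 and 0.05 without cKO 1, and adjusted p of Rps9 up to 0.148), while Rps2 lost its call without control 2, control 3 or cKO 1 (adjusted p up to 0.0671). The library labelled control 1 held 5 fragments of Y-linked genes, which only males carry. Control 2 and 3 held 5703 and 7120, and those labelled cKO 1, 2 and 3 held 8930, 3389 and 5971. Sex was not a term of the fit, and without control 1 there were 1637 calls. The first principal component, with 62.7% of the variance, separated the labelled groups. The second, with 19.8%, set the libraries labelled control 1 and cKO 3 apart from the other 4.

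**Figure D3:**
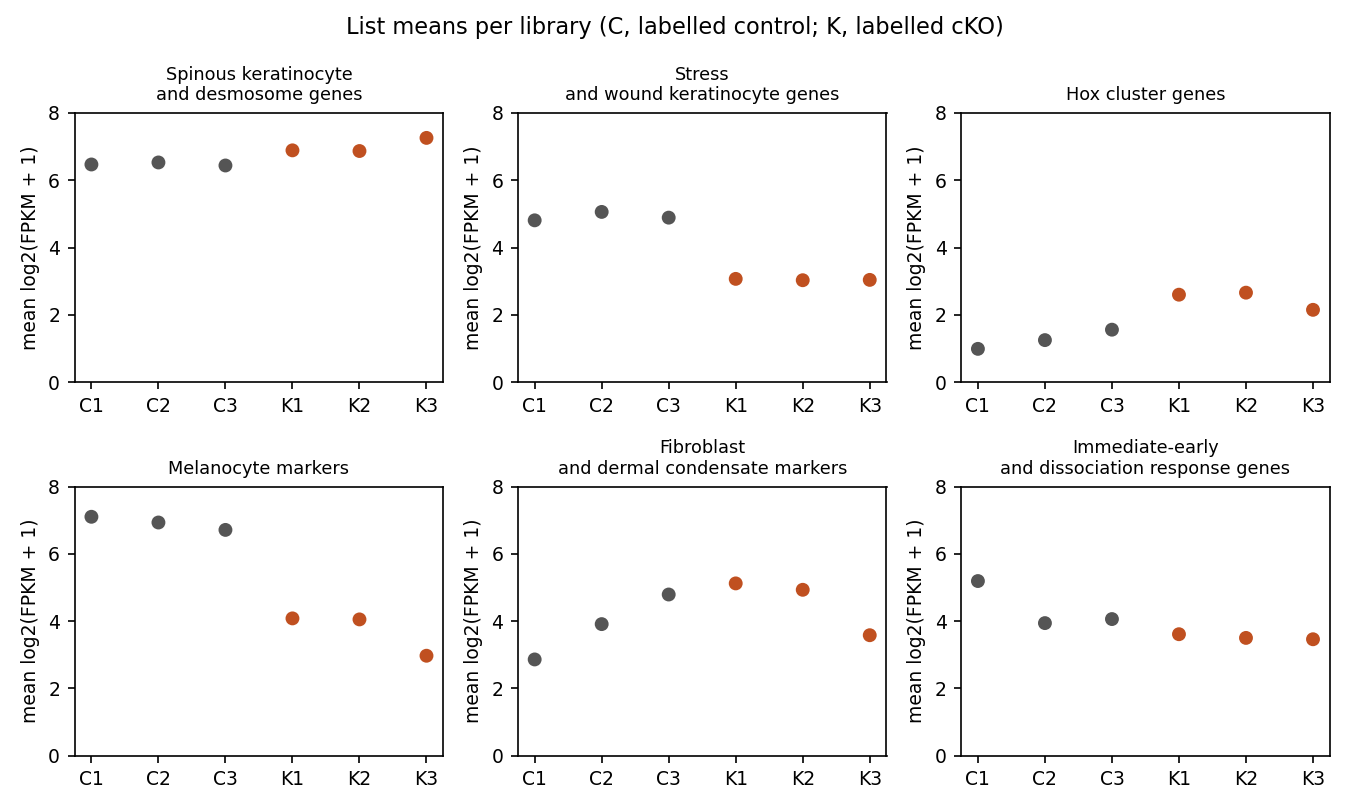
Mean log2(FPKM + 1) of 6 gene lists (vertical axes, from 0) in each library (horizontal axes). Melanocyte means were 7.10, 6.93 and 6.71 in the libraries labelled control and 4.08, 4.05 and 2.97 in those labelled cKO, while fibroblast means overlapped between the groups.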

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

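Tests chosen after the data were seen are limma-voom on the recovered fragments and the fit on 4 libraries. Ash2l stayed higher in the libraries labelled cKO under all 21 alternatives, between 0.67 and 1.04, and with 1 library left out between 0.67 and 0.94. It lost its call with the replicate block (0.81, adjusted p = 0.0613), where the cause was not tested, and with fewer libraries in 4 of the 6 fits that left 1 out; its adjusted p ranged from 0.000948 to 0.0829. The 2257 calls (681 higher and 1576 lower) became 4254 (1423 and 2831) with array weights and 1325 (432 and 893) with the replicate block. They became 3576 (1174 and 2402) on the 4 libraries labelled control 2 and 3 and cKO 1 and 2. The cause was not tested, but these 4 were the closest pair of each group (chi-square per gene 50.2 and 14.4), which lowers the spread. Quantile normalization gave 1028 higher, and limma-voom with the median of ratios 1043 lower. Both change the scaling, which moves the median of all genes. Other thresholds changed the counts by construction: 1268 (404 and 864) with a log2 difference of at least 1 as well, 2407 lower at adjusted p under 0.10, and 4030 (1175 and 2855) at unadjusted p under 0.05. With 1 library left out the calls ranged from 1102 to 2163, from 390 to 715 higher and from 712 to 1448 lower. Same-numbered libraries did not deviate together (correlations -0.31, 0.08 and -0.26), so no pairing by replicate number was seen. So few pairs cannot exclude it. The 10 pathway and cell state lists called became 0 with an estimated correlation, 6 with fry directional and 17 with fry mixed, and the 4 other cell type and quality lists became 0 with an estimated correlation and 2 with fry directional; these tests allow for correlation between genes or ask another question. The 10 list enrichments stayed within 1.5-fold under all alternatives. Of 136 named genes besides Ash2l, 96 were called; over 2004 pairs of a called gene and an alternative 1809 kept the call and 195 lost it, and no named gene or list reversed with a call. Boc, Shh, Wnt10b, Rpl3, Rpl10, Rps9, Ndufv1, Uqcrh and Tnnt3 lost theirs under at least 10, and Cd151, Cox6a1, Esam, Fzd10, Gins2, Itgb4 and Sox18 under 7 to 9. The simulated test recovered 4% of 1.5-fold changes. Its cut-off was stricter than that of the data, as it held fewer changed genes, so that share need not hold here. A gene that was not called may still differ by that much.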

Other observations

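All tests of explanations here, and the pathway enrichment, were chosen after the results were seen. Of 307 pathway terms of the authors' annotation, 12 were enriched among genes higher in the libraries labelled cKO and 36 among the lower. Enrichment was called at adjusted p under 0.05, and terms share genes. Retinol metabolism was enriched among the higher, with 12 of 30 genes called and 1.8 by proportion (one-sided Fisher's exact test, adjusted p = 2.73e-05). The 12 retinol metabolism genes included the retinol dehydrogenase genes Rdh12 (2.08), Rdh9 (1.30) and Rdh1 (1.29), with Adh1 (3.12), Cyp2w1 (2.69) and Sdr16c5 (1.73). Fatty acid elongation followed with 10 of 23 (adjusted p = 4.93e-05), among them Elovl4 (1.01), Elovl6 (1.11), Tecr (0.90) and Them5 (2.33). The 10 also held Acaa2 (1.15), Hadhb (0.85) and Hadh (0.73), which stand in the term for fatty acid degradation too. Acot7 (-1.16) and Ppt2 (-0.67) of the elongation term were lower. Among genes lower in these libraries, focal adhesion had 49 of 157 (23.8 by proportion, adjusted p = 4.93e-05), with Lama4 (-2.47), Met (-2.38), Ilk (-1.32), Zyx (-1.68) and Itgb1 (-1.57). NOD-like receptor signalling had 39 of 116 (adjusted p = 6.34e-05). These genes were named after their values were seen, and the directions rest on labels that Ash2l went against.

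Ash2l was higher in all 3 libraries labelled cKO than in any labelled control. Scaling alone did not account for it: over 3 other scalings the difference was at least 0.71, with adjusted p under 0.05 in each. Fewer keratinocytes in the libraries labelled control would lower all keratinocyte genes alike. The median difference of Krt5, Krt14, Cdh1 and Trp63 over all 6 libraries was 0.16, against 0.81 for Ash2l. Krt5 (0.51) and Trp63 (0.40) lay above 0, and Krt14 (-0.08) and Cdh1 (-0.09) just below it. On the 4 libraries labelled control 2 and 3 and cKO 1 and 2, Krt5 (0.60) and Trp63 (0.74) came near Ash2l (0.80). These genes therefore cannot exclude that the share of keratinocytes played a part. An exchange of the labels of the 2 groups may be the source and stays open. Column codes carry the letter C for the libraries labelled control and W for those labelled cKO. No label explains these letters, so they cannot decide it. The mean in the libraries labelled control was 55.7% of that in the libraries labelled cKO, which is neither the near loss that would decide for an exchange nor an order that would exclude it, and transcripts lacking a floxed exon can still be counted. Altered transcription of the targeted locus in the labelled cKO stays open as well and was not tested.

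All 13 melanocyte markers were lower in the libraries labelled cKO. Scaling left the median at -2.80 or lower. Fewer keratinocytes in the libraries labelled control would move all other cell types alike, but these moved apart by more than their spread. Fibroblast markers had a median of 0.75 (SD 0.84; 0.18 with SD 0.71 without the library labelled control 1), Merkel cell markers of -0.04 (SD 0.56) and endothelial markers of -0.33 (SD 0.71), against -2.96 (SD 0.72) for melanocyte markers. Schwann cell and neural markers (-1.01, SD 1.28) and skeletal muscle markers (-1.42, SD 1.33) went the same way as melanocyte markers and overlapped them within these spreads. The Schwann overlap ended without the library labelled cKO 3 (-0.60, SD 1.22, against -2.66, SD 0.71 for melanocyte markers). It also ended on the 4 libraries labelled control 2 and 3 and cKO 1 and 2 (-0.53, SD 1.11, against -2.63, SD 0.77). The muscle overlap stayed in both, but that list had only 3 tested members, with Mylpf at 0.02. A loss shared with those types stays open. Fewer melanocytes with the same content would keep the markers in 1 ratio only if no other cells added to their reads. Of the 13, 5 differed from the mean of the list (limma), Tyrp1 by -1.53 and Trpm1 by 1.12. Reads from other cells were not measured, so these ratios cannot decide against a change in number alone. A change in melanocyte number, alone or together with their state, by genotype or by the sort, may remain and was not tested.

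Hox genes were higher in the libraries labelled cKO. Over 3 other scalings the median was at least 1.28 and camera called the list each time. Limma-voom at the library total, which changes the model and not the scaling, called 11 of the 23 members, short of a first bound of at least 12 that was then replaced. More fibroblasts do not account for it alone: with the fibroblast mean as a covariate 15 Hox genes were higher and 1 lower adjusted over the list alone (median 1.12), against 17 and 0 without it (median 1.36). Skin from another position along the body may have been taken and stays open: paralogue groups 9 to 13 had a median of 0.24 with 0 of 5 called, and groups 1 to 8 a median of 1.41 with 13 of 18 called (exact permutation test over genes, one-sided, p = 0.00134, genes not being independent). A position effect cannot be told apart from one of genotype, since no label gives the position.

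With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The labelled split was the 1 split with as many genes called, 2257, and the highest of the others had 0 (limma). Each of the other splits mixed both labelled groups on each side. A difference between the groups then adds to the spread within a side and holds down the calls, so that 0 is no measure of chance. The labelled split was also the 1 split with as many lists called, 14, but the highest of the others had 13. The number of lists called by camera at the preset correlation thus hardly set the labelled split apart. Part of any group difference remains between the sides of a mixed split, so 13 is no measure of chance either.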
